A study of Caenorhabditis elegans with 2 samples.

How the data were processed

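Chromatin immunoprecipitation followed by sequencing was done, per the labels, on whole late embryos of a transgenic Caenorhabditis elegans strain that expresses T23F11.4 with a C-terminal green fluorescent protein and FLAG tag, with an antibody against green fluorescent protein. Worms of both sexes were pooled and synchronised by egg bleaching, and chromatin was fragmented by sonication, per the labels. Both samples belong to 1 group and are labelled as biological replicates 1 and 2. A control experiment is named in the labels and was not analysed here.

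Peak lists were used as deposited: 1 list per replicate, 1 called on the pooled reads of both replicates, and the optimal set that passed the irreproducible discovery rate threshold. Per the deposited notes that accompany the samples, the coordinates are in ce11, each of the 3 larger lists was made from alignments and a control, and these lists hold peaks and background without a threshold. The aligner, peak caller, their versions and the rate threshold are not given in the sources used here. The signal value per region was computed by the authors, and its relation to read depth is not given. The −log10 q-value per region, also from the authors' caller, ranged from 1.96 to 2.29 in the optimal set and was equal to its highest value for 487 of the 636 peaks, so it was not used to rank peaks. Each of the 636 optimal peaks equals a region of the pooled list, and no other region of that list has as high a signal value. The deposited optimal set thus carries the pooled values. The median width of optimal peaks is 444 bp, and 2 intervals appear a second time with another summit. Read counts were not in the lists, so depth is unknown and no error from depth could be computed. Coverage tracks were not used here.

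Coordinates in ce11 were joined to the WBcel235 assembly, to Ensembl release 115 gene models and, for tRNA names and amino acids, to the RefSeq annotation of WormBase WS298. All peaks on the 6 nuclear chromosomes ended within the chromosome lengths of that assembly. Coordinates are given counting from 1. The 1 optimal peak on the mitochondrial genome was left out of every test, leaving 635. The background was the 29163 nuclear regions of the pooled list that overlap no optimal peak, since they could have entered the optimal set.

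Shares of peaks were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 9 RNA gene classes, 7 features or 28 gene lists. A gene was called bound if an optimal summit lay within 1000 bp of any of its transcript starts, and an RNA gene if one lay within 500 bp. Each feature class took a summit once, in the order promoter, 5' UTR, 3' UTR, coding exon, exon of a non-coding gene, intron and intergenic. Replicate support, and the numbers of snoRNA and tRNA genes with a peak, were set beside 1000 circular shifts of the peaks along their chromosomes. Signal was compared by permutation with 100000 resamples. Presence of each canonical 6-mer was compared by an exact McNemar test. Pairs of replicates were described by correlation across regions, which are not independent samples. All p-values from peaks and genes describe these 2 pooled replicates and do not measure variation between further animals. GC content, amino acids of tRNA genes, uniqueness of 32-mers and the mitochondrial regions of each list were examined after the main values had been seen. snRNA genes were split after seeing the data into spliced leader genes by name and U6 genes by a match to the conserved U6 core.

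The genes named were set by a rule. It takes every protein-coding gene with a start within 1000 bp of the 20 strongest optimal summits (or the nearest start), the RNA gene nearest to each within 500 bp, up to 4 bound members with the strongest peak in each list with an adjusted p under 0.05, T23F11.4 and unc-119, and the 5 enriched 6-mers with the smallest p. The tests, lists, rule and alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were the 317 strongest peaks, the 635 strongest regions of each replicate alone, the interval midpoint, other distances (200, 500, 1000 and 2000 bp), random positions (10 per peak) or the strongest other regions as background, other overlaps, only the nearest gene, 7-mers, a narrower window and matched regions. Settings without peaks near tRNA, snoRNA, snRNA or rRNA genes were added after seeing the data.

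The scripts were tested on simulated data. Of 2080 6-mers, 0 were called with none planted, and a 6-mer planted in 20% of windows was recovered. The simulated windows came from random positions and lacked the GC difference between the real summits and flanks (medians 47.8% and 36.3%). The 0 calls thus do not cover 6-mers called through that difference. For the gene lists, 1 list was called over 20 simulated data sets of 19973 genes with no change, and 41 of 100 lists whose bound share was raised 4-fold were recovered, so a list that does not pass can still differ. Each simulated gene was drawn on its own, whereas in the data 1 summit can count for several genes. The simulated calls thus do not cover lists whose members share peaks. For the promoter share, 5 of 100 random peak sets were called, and 87 of 100 were called with 10% of positions moved to starts. Analyses used python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.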

Results

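The binding of the T23F11.4 protein, annotated as carrying a zinc finger domain, was mapped by chromatin immunoprecipitation and sequencing in late embryos of Caenorhabditis elegans. The worms carried a transgene of T23F11.4 fused to green fluorescent protein, together with a rescuing copy of unc-119, and an antibody against green fluorescent protein was used. The series held 1 group with 2 biological replicates, and the label gave an age of 4 hours. With no second group, the comparisons below set the authors' optimal peaks against other regions of the same data and 1 replicate against the other. The authors' optimal set, named for its irreproducible discovery rate threshold, held 636 peaks, 635 of them on the nuclear chromosomes. These were the strongest regions of a list of 30000 regions called on the pooled replicates. The lists of replicate 1 and replicate 2 held 30000 and 25802 regions. Read depth was not given in the sources used here, so depth limits could not be set for any region. The signal value per region is the authors' own and was used only to describe and rank regions within a list. Binomial intervals are Wilson 95% intervals and cover counting error only.

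The first comparison asked how far both replicates gave the same peaks. Ranks are among nuclear regions throughout. All 20 of the strongest optimal peaks, 10 of them near snoRNA genes, were among the 635 strongest regions of each replicate. The strongest, next to the snoRNA gene W03C9.9, ranked 1 in replicate 1 and 2 in replicate 2. Over the whole set, 393 of 635 peaks (61.9%, interval 58.1% to 65.6%) overlapped one of the 635 strongest regions of both replicates by at least 1 bp. Another 66 peaks did so in replicate 1 alone, 159 in replicate 2 alone and 17 in neither. The optimal peaks came from the pooled reads of these same replicates and had passed a reproducibility threshold, so overlap far above that of random positions (a mean of 0.329% over 1000 circular shifts) was fixed by their selection and is not evidence of agreement.

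Signal rose together in both replicates. Across the 635 peaks, which are regions and not independent replicates, Spearman's rho was 0.597 and Pearson's r of the log2 signal was 0.75 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Each peak took the signal of the strongest overlapping region in a replicate, so neighbouring peaks can share values. With the region of the nearest summit in its place, rho was 0.555. Pearson's r was 0.86 across the 50 strongest peaks and 0.557 across the other 585. The optimal peaks are the top of the pooled ranking, which narrows the range these correlations cover. The signal values are on different scales in the 2 lists, with a median ratio of replicate 2 to replicate 1 of 1.75 and an SD of the log2 ratio of 0.45.

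**Figure D1:**
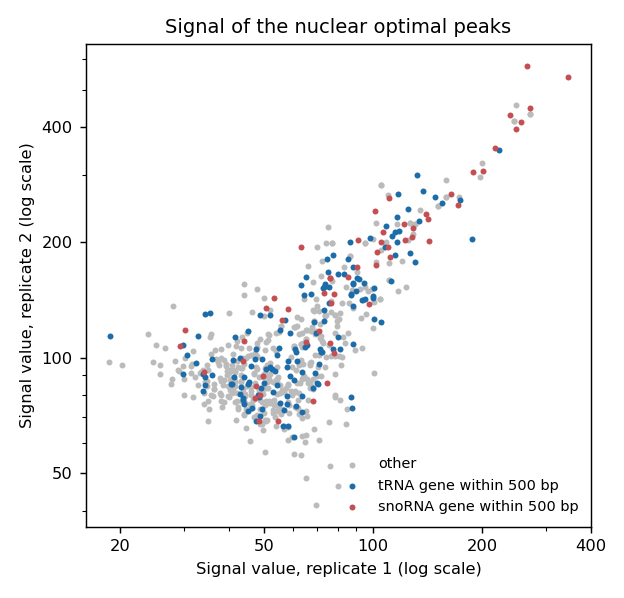
Signal value of the strongest region that overlaps each of the 635 nuclear optimal peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales. Peaks within 500 bp of a snoRNA or tRNA gene are in colour, and neighbouring peaks can share values. Signal in both replicates rises together over the 635 peaks (Pearson's r of the log2 signal 0.75, with 0.86 across the 50 strongest and 0.557 across the others).

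The next comparison concerned the sites of strongest signal. Of the 20 strongest optimal peaks, 10 lay within 500 bp of a snoRNA gene, whose products guide the chemical modification of other RNAs, and 3 lay within 500 bp of a tRNA gene. The strongest of all, at II 11960655 to 11961022 in ce11 (signal 887.5; 347.1 in replicate 1 and 539.8 in replicate 2), was intergenic, and its summit lay 63 bp from W03C9.9. The second, at V 12303473 to 12303825 (signal 853.5), had its summit inside the snoRNA gene C51F7.4. The third, at V 11314060 to 11314379 (signal 717.8), was intronic and lay 47 bp from the snoRNA gene T03F7.8 and 12 bp from the ncRNA gene T03F7.14.

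The other snoRNA genes at these 20 peaks were ZK994.7 (signal 677.8), ZK265.10 (665.4), T06C12.16 (639.8), T02E1.9 (565.5), Y43F8C.22 (507.5), C04G6.12 (496.7) and C10C6.8 (436.4). The summit at C10C6.8 also fell inside the ncRNA gene C10C6.11. The tRNA genes were C04A11.t1 (a leucine tRNA, signal 568.5), C42D8.t1 (isoleucine, 432.6) and T21B4.t1 (isoleucine, 430.6). The summit at C42D8.t1 also fell inside the ncRNA gene C42D8.14, and that at T21B4.t1 inside T21B4.19. One further peak lay 54 bp from the microRNA gene mir-51, inside the ncRNA gene F36H1.17 (signal 495.9).

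Protein-coding starts within 1000 bp of these 20 summits belonged to K12H4.5 (signal 712.7), sre-23 (665.4), ftt-2 (656.3), C04A11.5 (568.5), T02E1.2 (565.5), rpl-3 (526.6), Y43F8C.7 (507.5), mpk-2 (496.7), C14F11.7 and T13C5.6 (448), atx-2 and ecps-1 (434.1), and col-85 (430.6). Of these, ftt-2 encodes a 14-3-3 protein, rpl-3 a protein of the large ribosomal subunit, mpk-2 a MAP kinase and col-85 a collagen. The summits at ftt-2 and at C14F11.7 and T13C5.6 also fell inside the ncRNA genes F52D10.7 and C14F11.14. For the other 9 peaks the nearest protein-coding starts were those of F55C5.17 (1098 bp away), ets-5 (1105 bp), W03C9.1 (1293 bp), str-56 (1404 bp), T23F11.4 (1523 bp), cutl-18 (2690 bp), hrg-5 (3019 bp), wht-2 (3811 bp) and pxn-1 (5683 bp).

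Short non-coding RNA genes were then compared over the whole set. tRNA genes lay within 500 bp of 148 of 635 optimal summits (23.3%, interval 20.2% to 26.8%) and of 280 of 29163 other regions of the pooled list (0.96%). snoRNA genes lay near 57 optimal summits (8.98%, interval 6.99% to 11.5%) and 175 other regions (0.6%). The odds ratios were 31.3 for tRNA genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 9 classes, p = 1.27e-138) and 16.3 for snoRNA genes (adjusted exact p = 3.94e-43). Genes annotated as ncRNA (38.3% against 10.4%, adjusted exact p = 8.17e-73), microRNA genes (1.89% against 0.384%, adjusted exact p = 3.23e-05) and snRNA genes (1.26% against 0.178%, adjusted exact p = 7.06e-05) were also more frequent near optimal peaks. A summit can count for more than 1 class, and some ncRNA genes overlap a tRNA gene, as C42D8.14 does C42D8.t1. The ncRNA share thus partly recounts summits near tRNA and snoRNA genes. Pseudogenes were less frequent (1.57% against 3.34%, adjusted exact p = 0.0144). piRNA genes (1.89% against 1.99%, adjusted exact p = 1) and lincRNA genes (0.787% against 0.487%, adjusted exact p = 0.318) did not pass the test. Among the 635 strongest nuclear regions of each replicate alone, 20.6% in replicate 1 and 22.4% in replicate 2 lay near a tRNA gene, and 8.66% and 8.98% near a snoRNA gene. No rRNA gene lay within 500 bp of any nuclear region in either set, so binding there was not assessed.

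**Figure D2:**
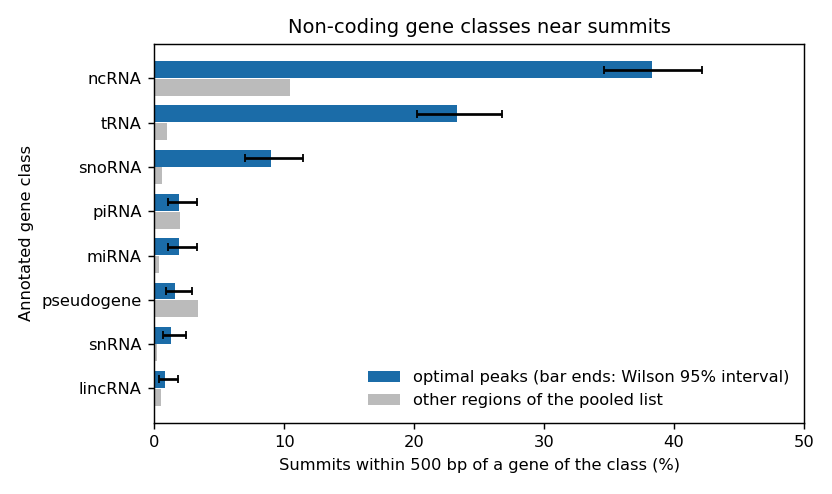
Percentage of summits within 500 bp of a gene of each non-coding class (x axis) for the 635 nuclear optimal peaks (blue, with Wilson 95% intervals) and the 29163 other regions of the pooled list (grey). The tRNA bars stand at 23.3% and 0.96%, and the snoRNA bars at 8.98% and 0.6%.

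Counted by gene, 168 of 612 nuclear tRNA genes (27.5%) and 58 of 346 snoRNA genes (16.8%) had an optimal summit within 500 bp. Circular shifts of the peaks gave means of 4.61 and 2.44 genes and at most 16 and 8 in 1000 shifts. A region of the pooled list, of any signal, lay near 445 of the tRNA genes and 197 of the snoRNA genes. Genes without an optimal peak can thus carry a weaker region, and the split is a cutoff on signal. tRNA genes for every standard amino acid were among those with a peak, from 15% of the 20 asparagine tRNA genes to 46.2% of the 13 cysteine tRNA genes, and these shares were not tested against each other. Most tRNA genes with a peak have copies of identical sequence elsewhere, since 29 of the 168 have a sequence that occurs once in the nuclear genome. All 58 snoRNA genes with a peak have a sequence that occurs once. Summits sat a median of 49 bp upstream of the annotated snoRNA gene start (a median position of -49 bp over 57 peaks), with 7 of the 57 inside the gene. At tRNA genes the median position was 29.5 bp downstream of the start over 148 peaks, and 95 lay inside the gene.

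Peaks at snoRNA genes were also the stronger ones within the optimal set. Their median signal was 261.5 (57 peaks), against 168 for the other peaks at tRNA genes (148 peaks) and 139.4 for the rest (430 peaks). The difference in median log2 signal from the rest was 0.91 for snoRNA peaks and 0.27 for tRNA peaks (two-sided permutation test with 100000 resamples, p = 1e-05 for each, the smallest it can give). Along the pooled ranking, snoRNA genes were near 38% of regions 1 to 50 and 4.26% of the last 235 optimal peaks, and tRNA genes near 24% and 14.5%. Just below the optimal set, at ranks 636 to 1270, the shares were 2.83% for snoRNA genes and 7.09% for tRNA genes.

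**Figure D3:**
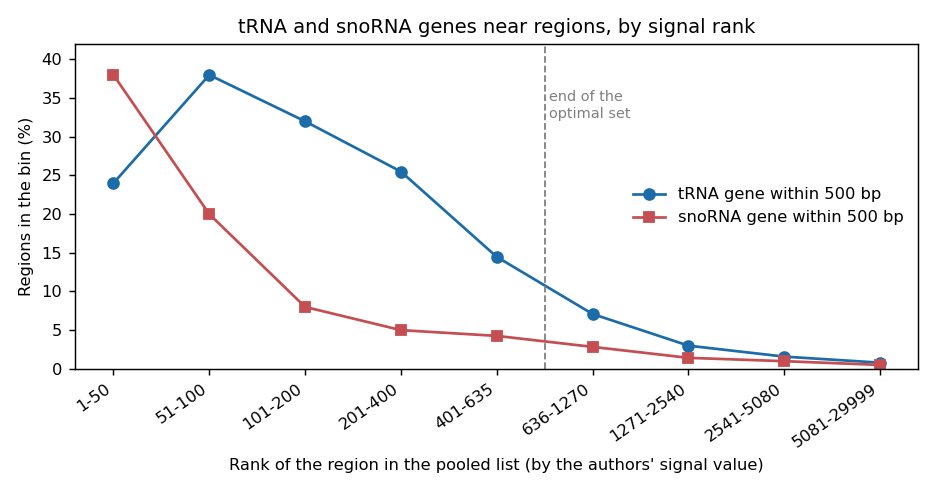
Percentage of regions (y axis) with a tRNA gene (blue) or snoRNA gene (red) within 500 bp, in bins of rank in the pooled list (x axis, strongest at left), with a dashed line at the end of the optimal set. The snoRNA share falls from 38% in the first bin and the tRNA share from 38% in the bin of ranks 51 to 100.

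Protein-coding promoters made up much of the set as well. Optimal summits lay within 1000 bp of a protein-coding start in 362 of 635 cases (57.0%, interval 53.1% to 60.8%), against 13073 of 29163 other regions (44.8%; odds ratio 1.63, two-sided Fisher's exact test, p = 1.26e-09). In each replicate alone the share was 55.9% (replicate 1) and 55.3% (replicate 2). By annotated feature, 315 summits (49.6%) lay in promoters, reaching 1000 bp upstream and 200 bp downstream of a start, against 29.9% of other regions (adjusted over 7 features, Fisher's exact p = 2.03e-24). Exons of non-coding genes held 20.3% against 3.35% (adjusted exact p = 2.81e-57). Coding exons (2.2% against 20.7%, adjusted exact p = 2.98e-43), introns (12.4% against 25.03%, adjusted exact p = 1.71e-14), 3' UTRs (0.472% against 2.46%, adjusted exact p = 0.0003) and intergenic sequence (14.8% against 18.1%, adjusted exact p = 0.0427) held fewer. The 5' UTR class, which the promoter class largely takes in by its priority, held 1 summit and did not pass the test (adjusted exact p = 0.384). Promoter peaks had a median signal of 146 and other optimal peaks 147.9, a log2 difference of -0.02 that was not distinguishable from 0 (two-sided permutation test, p = 0.715).

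The chromosomal distribution of the peaks was compared next. The X chromosome carried 156 of 635 optimal peaks (24.6%, interval 21.4% to 28.1%) and 5009 of 29163 other regions (17.2%; odds ratio 1.57, two-sided Fisher's exact test, p = 3.65e-06). X also carries 276 of the 612 nuclear tRNA genes, and 70 of the 148 optimal peaks at tRNA genes were on X. Without peaks and regions near tRNA genes, a setting chosen after seeing the data, X carried 86 of 487 peaks (17.7%) and 16.96% of other regions (odds ratio 1.05, Fisher's exact p = 0.67). Without those near tRNA, snoRNA, snRNA or rRNA genes, chosen likewise, the share was 20.3% (odds ratio 1.24, Fisher's exact p = 0.0785). Against the 635 strongest other regions alone, the X share did not pass the test (odds ratio 1.24, Fisher's exact p = 0.123). On the autosomes, 272 of 479 peaks (56.8%, interval 52.3% to 61.1%) lay in the central 50% of the chromosome, against 45.4% of other regions (odds ratio 1.58, Fisher's exact p = 8.26e-07). Against uniform positions along the autosomes, another planned background, the central share was only 1.14 times as high. The outer parts held the remaining 207 peaks.

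The protein-coding genes with a bound promoter were then grouped by 28 lists. Of the 19973 nuclear protein-coding genes, 2.34% had an optimal summit within 1000 bp of a start. A higher share was found in 5 lists and a lower share in 1 (Fisher's exact test, two-sided, adjusted over the 28 lists). Cytosolic ribosomal protein genes stood highest, with 13 of 82 bound (15.9%; odds ratio 8.07, adjusted exact p = 7.61e-07). The strongest peaks in that list were at rpl-3 (signal 526.6), rpl-35 (244.3), rpl-20 (227.5) and rps-28 (224).

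Epidermis and cuticle genes followed, with 7 of 61 bound (11.5%; odds ratio 5.48, adjusted exact p = 0.00391), led by the cuticle component gene cut-2 (signal 203.2), the alpha spectrin gene spc-1 (202.1), the collagen gene dpy-17 (177.6) and the beta spectrin gene unc-70 (148.6). Of the protein folding and stress genes, 7 of 67 were bound (10.4%; odds ratio 4.93, adjusted exact p = 0.0053), with the chaperone genes hsp-3 (270.25), hsp-1 (206.8), hsp-60 (201.9) and dnj-19 (174.1) strongest. Of these 7, 2 gene models carry the same name, hsp-16.48, and share 1 peak. Of the chromatin regulators, 8 of 80 were bound (10%; odds ratio 4.7, adjusted exact p = 0.00391), led by the acetyltransferase gene cbp-1 (211.1), the histone demethylase gene jmjd-1.2 (206.5), the chromatin remodelling gene swsn-7 (197.5) and lem-2 (188), which encodes a protein of the nuclear envelope. Of the cell cycle and DNA replication genes, 8 of 93 were bound (8.6%; odds ratio 3.98, adjusted exact p = 0.00705), with the retinoblastoma homologue lin-35 (180.7), the centriole gene sas-5 (168.8), the centrosome gene spd-5 (157.9) and the spindle checkpoint gene mdf-2 (149.1) strongest. The peak at mdf-2 lay 21 bp from a tRNA gene.

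Chemoreceptor genes had a lower share, with 3 of 1310 bound (0.229%; odds ratio 0.09, adjusted exact p = 4.13e-09). Those bound were sre-23 (signal 665.4, 58 bp from a snoRNA gene), sre-1 (253.4) and sri-5 (171.1). The other 22 lists did not pass, among them neurons (4 of 77), collagens (4 of 156), homeobox genes (2 of 95) and nuclear hormone receptors (4 of 274). Some bound genes share a peak, as lin-54 of the cell cycle list does with rpl-12. Of the lists that passed, only the ribosomal protein and chemoreceptor lists did so in every setting run, with odds ratios of 4.76 and 0.166 where only genes with a pooled region near a start were compared. With starts within 500 bp, only the ribosomal protein and cell cycle lists of the 5 passed. The epidermis list fell there to 1.64% bound (adjusted exact p = 0.882). With only the nearest gene, the cell cycle list fell to 4.3% bound (adjusted exact p = 0.308). The protein folding list fell there to 4.48% (adjusted exact p = 0.381). With the 317 strongest peaks, the cell cycle (adjusted exact p = 0.11) and chromatin (adjusted exact p = 0.0801) lists did not pass. Among genes near a pooled region, the cell cycle (adjusted exact p = 0.091) and epidermis (adjusted exact p = 0.0581) lists did not pass. Without replicate 2 the epidermis list stood at 6.56% (adjusted exact p = 0.153).

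**Figure D4:**
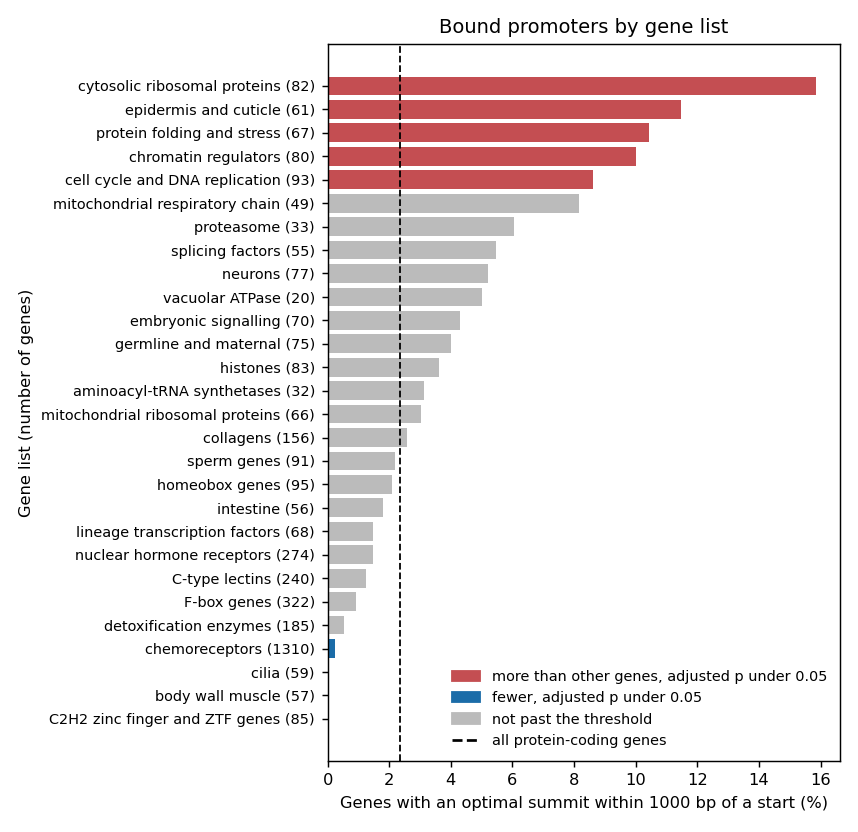
Percentage of the genes of each of the 28 lists with an optimal summit within 1000 bp of a start (x axis), with the number of genes in brackets and a dashed line at the 2.34% of all protein-coding genes. The 5 red lists, from 15.9% down to 8.6%, had more bound genes than other genes, and the blue chemoreceptor list, at 0.229%, had fewer.

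The loci present in the transgene were examined in every list. T23F11.4 lies on III from 4663174 to 4665372, and its neighbourhood held 4 optimal peaks within 5 kb. A double peak in 1 interval, 4666781 to 4667195, had summits at 4666895 (signal 696.9, rank 5) and 4667096 (signal 403, rank 26), 1523 and 1724 bp upstream of the start. Both summits lay inside the ncRNA gene T23F11.9, and the second also inside T23F11.8. In replicate 1 the corresponding regions had signals of 272.1 (rank 2) and 145.8 (rank 26), and in replicate 2 they had 432 (rank 5) and 144.5 (rank 135). Weaker optimal peaks had summits at 4662894 (signal 134.6) and 4668300 (signal 118.9). At unc-119, on III from 10902641 to 10908935, no optimal peak was found within 5 kb. The pooled list held 4 regions there, the strongest with a signal of 50.2 (rank 12437). The strongest in the replicate lists had 40.5 in replicate 1 (rank 1079) and 37.2 in replicate 2 (rank 9462). Reads from the transgene and from the native loci cannot be separated in these lists.

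Short sequences at the summits were compared with the flanks of the same peaks. Of 2080 canonical 6-mers, 508 were more frequent within 100 bp of the summit than in a window centred 500 bp to one side, and 403 were less frequent (exact McNemar test, two-sided, adjusted over all 6-mers). The 5 with the smallest p among the enriched ones were GAGAGA, AGAGAG, CCGCCC, CGCGCA and CCCCGC. GAGAGA was present at 227 of 635 summits (35.7%) and 72 flanks (11.3%; adjusted exact p = 6.52e-23), and AGAGAG at 30.6% and 8.03% (adjusted exact p = 6.52e-23). CCGCCC was present at 17.3% of summits and 2.2% of flanks (adjusted exact p = 1.66e-18), CGCGCA at 17.95% and 2.83% (adjusted exact p = 1.08e-17), and CCCCGC at 15.4% and 1.57% (adjusted exact p = 1.85e-17). Median GC content was 47.8% at summits and 36.3% on either flank. Against other regions of the pooled list matched on GC content and distance to a start, 178 6-mers were enriched, and all 5 named above were among them, at smaller differences than against the flanks. GAGAGA was present at 35.7% of summits and 17.01% of matched regions (adjusted Fisher's exact p = 3.73e-11), AGAGAG at 30.6% and 16.38% (adjusted exact p = 3.55e-07) and CGCGCA at 17.95% and 6.14% (adjusted exact p = 1.43e-08). CCCCGC was present at 15.4% and 7.09% (adjusted exact p = 0.000113), and CCGCCC, with the smallest ratio, at 17.3% and 11.02% (adjusted exact p = 0.014).

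The leading 6-mers were also listed by class, and differences between the classes were not tested. Among the 212 peaks within 500 bp of a tRNA, snoRNA, snRNA or rRNA gene, the leading 6-mer was GTTCGA, present at 59.0% of summits and 7.08% of flanks (adjusted exact McNemar p = 1.56e-23). GTTCGA matches the start of the B box, a promoter element inside tRNA genes treated below, and 96.4% of tRNA genes had a B box. The class was defined by nearby genes of this kind, so the excess of GTTCGA follows largely from that definition. Among the other 423 peaks the leading 6-mer was CACACA, present at 36.2% and 7.8% (adjusted exact p = 3.6e-21). These class-wise 6-mers were chosen after the values were seen. GAGAGA passed the test in both classes, at 28.8% of summits in the first and 39.2% in the second, while CGCGCA did not pass in the first (6.6% of summits and 2.83% of flanks, adjusted exact p = 0.244).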

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

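The test on copies of tRNA genes, the count of unique 32-mers, the settings without peaks near tRNA genes or near the 4 short RNA classes as alternatives for X, the test of the double peak's height and the test of bound tRNA genes on X were chosen after the result was seen; the other tests in this part were set before their values were computed, though the patterns themselves had been seen. The optimal set held 1 mitochondrial peak, outside the nuclear comparisons, at 1065 to 1508 of the mitochondrial genome with a signal of 280.3 and rank 78 over all optimal peaks. Its summit lay in an rRNA gene (898 to 1593). The list of replicate 2 held an overlapping region (signal 267.4), and that of replicate 1 held none. The replicate lists held 6 and 8 mitochondrial regions and the pooled list 1. The highest signal of any region in each replicate was mitochondrial, at 8878 to 9341 in replicate 1 (433.7) and at 8923 to 9362 in replicate 2 (720.9). No control samples were analysed here to set a background for these regions.

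Of the 20 strongest peaks, 10 lay near snoRNA genes, 3 near tRNA genes and 7 near neither. Copies of the snoRNA genes themselves do not account for the snoRNA part. Of the 58 bound snoRNA genes, 100% have a sequence that occurs once (interval 93.8% to 100%), and 53 have no 32-mer that occurs elsewhere. Only 7 of the 57 summits lay inside the gene, and copies of the sequence upstream were not examined, so reads shared there stay open. Reads shared between copies of tRNA genes stay open as well: 1 of 168 bound tRNA genes has only 32-mers that occur once, the median share of such 32-mers is 0% in bound and in unbound genes, and the odds ratio of a sequence that occurs once, bound against unbound, was 0.626 (Fisher's exact test, p = 0.0519). Signal at any strongly transcribed promoter may also contribute: 15.9% of ribosomal protein promoters and 16.8% of snoRNA genes were bound (odds ratio 0.936, Fisher's exact p = 1), a test that leaves this open, and the control was not analysed here. These shares used unlike windows, 1000 bp around starts and 500 bp around snoRNA genes, and do not compare peak heights. Of the bound ribosomal protein genes, rps-26 and rpl-7A had their strongest peak within 500 bp of a snoRNA gene. The design has 1 group and so gives no biological explanation for this pattern, and the B box test among the other observations compares only bound with unbound snoRNA genes.

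Extra copies of the transgene's genomic insert may raise the signal around T23F11.4. Other regions within 15 kb, outside optimal peaks, had a median signal of 59.98 (5 regions). This lay at percentile 97.9 of the same median around 9475 random genes (median 46.4, 95th percentile 56.7). Around unc-119, the rescue marker, the percentile was 56.9 (13 regions). The 15 kb around unc-119 may reach past the marker copy, so that percentile is no control for extra copies. Of the 8 other regions within 15 kb, optimal peaks included, the highest had 3.9 times and the median 1.48 times the median around random genes. The height the double peak would have without extra copies was not measured, so how much of it they account for stays open. Binding of the protein next to its own gene was not tested and stays open as well.

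The higher share of optimal peaks on X is consistent with the location of tRNA genes. Without peaks and regions near tRNA genes the odds ratio was 1.05 (Fisher's exact test, p = 0.67), where it had been 1.57. Of tRNA genes on X, 30.8% were bound, against 24.7% on autosomes, a difference that did not pass the test (odds ratio 1.36, Fisher's exact p = 0.102). Without peaks near any of the 4 short RNA classes the odds ratio was 1.24 (Fisher's exact p = 0.0785), so an effect of X itself on the remaining peaks stays open.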

How the results depend on the processing

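Of 51 alternatives for the 8 main results with a test, 44 kept their direction and their side of the threshold. This tally overstates stability, since it includes settings that could hardly change a result. The midpoint gave the same shares as the summit at promoters, on X, in centres and at tRNA and snoRNA genes. The settings for replicate overlap could hardly fail either, given how the peaks were selected. For the 4 main results that are counts, 23 of 29 alternatives stayed within 1.5 times the main count and 11 equalled it. A count within that range can still hide lost calls: features that differed fell from 6 to 5 with the 317 strongest peaks, without replicate 1 and without the 4 short RNA classes, RNA classes fell from 5 to 4 with the 317 strongest peaks, and 6-mers ranged from 373 to 525. The count for 7-mers (693) is drawn from more words and was left out of this comparison. Settings without peaks near tRNA genes, or near tRNA, snoRNA, snRNA or rRNA genes, were chosen after seeing the data. The shares at promoters, in chromosome centres, at tRNA genes and at snoRNA genes passed under every setting run, as did rho (0.441 to 0.702). Against the 635 strongest other regions, the odds ratio fell to 1.32 at promoters (Fisher's exact p = 0.0155) and to 1.32 in centres (Fisher's exact p = 0.0347). The shares at tRNA and snoRNA genes were not tested against those regions. In the pooled ranking, ranks 636 to 1270 had a tRNA gene near 7.09% of regions and a snoRNA gene near 2.83%. Over all other regions the shares were 0.96% and 0.6%, so the odds ratios of 31.3 and 16.3 rest partly on weak background regions. Replicate overlap, high by the selection of the peaks, ranged from 54.8% to 94.0%. The X share lost its call against the 635 strongest other regions (24.6%, Fisher's exact p = 0.123), without peaks near tRNA genes (17.7%) and without those near any of the 4 classes (20.3%). The last 2 of these settings both leave out the peaks near tRNA genes, with odds ratios of 1.05 and 1.24. The location of tRNA genes is weighed above, and for the strongest other regions the cause was not tested. The number of lists with more bound genes fell from 5 to 3 with the 317 strongest peaks, with only the nearest gene and with only genes near a pooled region, and to 2 with starts within 500 bp, and rose to 6 with starts within 2000 bp and without replicate 1. The ribosomal protein and chemoreceptor lists kept their calls in every setting run, with odds ratios of 4.76 to 11.2 and 0.0452 to 0.2. Enriched 6-mers fell from 508 to 178 against matched regions, and RNA classes from 5 to 2 without the 4 classes, which that setting removes by construction. The promoter signal difference, not past the threshold in any setting, changed sign with starts within 2000 bp (0.021), without the 4 classes (0.057) and without either replicate (0.021 to 0.11). The 635 strongest pooled regions are the optimal peaks themselves, so that alternative for rho says nothing about stability. Leaving out a replicate has no meaning for replicate overlap and rho, which need both. Read depth is unknown, so what it limits could not be assessed. No paired analysis was possible because there is 1 group.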

Other observations

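The test of neighbouring tRNA genes and the strand and position of B boxes below were chosen after the result was seen, and the classes of short RNA genes in the next sentences were named after their values were seen. The genes for the RNA components of RNase P and RNase MRP, rpr-1 and mrpr-1, which process tRNA and rRNA precursors, both had an optimal peak (signals 417.2 and 289.1). SL2 spliced leader genes had one at 5 of 18 copies (27.8%), and U6 snRNA genes, the splicing RNA made by RNA polymerase III, at 3 of 22. None of the other 77 snRNA genes had one, though 35 of them had a region of the pooled list within 500 bp. The Y RNA gene yrn-1, the 12 SL1 genes and the 16 5S rRNA genes had no region in the pooled list, so binding there was not assessed. Among microRNA genes, 15 of 261 had an optimal peak, among them mir-51 (495.9) and mir-52 (375.9).

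A hypothesis was tested on what sets the 58 bound snoRNA genes apart from the 288 others. The B box is a promoter element inside tRNA genes, bound by the RNA polymerase III factor TFIIIC. A B box lay within 200 bp of 25 bound snoRNA genes (43.1%) and 29 unbound ones (10.1%; odds ratio 6.77, Fisher's exact test, p = 1.58e-08). Neighbouring annotated tRNA genes do not account for this, as all 58 bound snoRNA genes lay further than 500 bp from one. The 2 snoRNA genes within that distance were unbound. Leaving them out could thus hardly change the odds ratio (6.71, Fisher's exact p = 1.8e-08). Of the 25 bound genes, 23 had a B box on their own strand, which began upstream of the gene in 22. The neighbours C51F7.3 and C51F7.4, named after their values were seen, share the same boxes, which lie upstream of C51F7.3 and begin inside C51F7.4. Many bound snoRNA genes may thus have an RNA polymerase III type of promoter, while the other bound snoRNA genes had no such match. Within 100 bp of the summit a B box was present at 90.5% of peaks near tRNA genes, 40.4% of peaks near snoRNA genes, 2.84% of peaks near none of the 4 short RNA classes and 3.14% of other regions.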
